A study of Mus musculus with 6 samples.

How the data were processed

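Whole lungs of male mice were dissociated to single cells, and droplet libraries of the 3′ ends of transcripts were made with 10x Genomics v3.1 chemistry, per the labels' protocols. The labels give 6 lungs, 3 from AlbCre control mice and 3 from BHLKO mice, as separate animals. The series text puts collection at zeitgeber time 4 and the protocol text at circadian time 4, and the difference was not resolved here.

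The data used here were 2 lists for the whole series, as the authors deposited them: the cell barcodes kept after filtering, and the genes that reads were counted against. Both hold text and no measurement. Cell Ranger and STAR, with the build mm10, are named per the submitters' processing notes, with no version. The annotation release and the rule by which barcodes were called cells are not given in the sources used here. Doublets were not assessed, and whether the authors removed them is likewise not given, so a barcode can hold more than 1 cell. Each barcode is a sequence of 16 bases followed by a library number from 1 to 6. No label or file ties a library number to a lung, so libraries are named by number, were put in no genotype, and 0 columns of values were assigned to a sample. Counts per gene and cell were not analysed here, so the depth in reads or molecules is unknown, and expression, cell types and their shares were not measured.

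Barcodes were counted per library, and each library's share of all barcodes was given with a 95% exact (Clopper-Pearson) binomial interval, which covers counting error only. Sequences present under more than 1 number were counted for each of the 15 pairs of libraries. Libraries that draw beads independently share barcodes in proportion to the product of their sizes, so the shared barcodes were dealt to pairs at random in that proportion. A one-sided Monte Carlo test with 100000 draws compared the summed squared deviation from expectation, and each pair had a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 15 pairs. The number of sequences the libraries drew from was estimated as the summed products of library sizes divided by the shared barcodes, with an exact Poisson interval. The procedure was tested on simulated libraries of the same 6 sizes. Of 100 simulations without excess sharing, 6 passed the 0.05 threshold and 98 had the true pool size inside the interval. Of 100 with 30 extra barcodes shared by libraries 2 and 5, 100 passed. A smaller excess of 8 barcodes in libraries 4 and 5, chosen after seeing the data to match the observed excess of 8.31, passed the Monte Carlo test in 75 of 100 simulations and the test of that pair in 76. With the pool size estimated from the other pairs (3940050 in place of 5000000), these were 59 and 69 of 100.

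Gene identifiers were matched to GENCODE release M21, an annotation of GRCm38, the assembly that mm10 denotes. Of 32285 identifiers, 32235 (99.8%) were found and 50 were not. The symbol differed from that in M21 for 733 of those found, so the list was not made from M21 as it stands. Coordinates are those of M21, counted from 1. The genes named were fixed before the data were examined: Hif1a and Arntl (the annotation's symbol for Bmal1), Alb, and all members of 4 lists (clock, hypoxia response, vascular tone and hepatocyte genes), with 28 lists of lung cell type markers. Not every member is reported here by name. Shared exon bases were counted between listed genes on the same strand. The gene model shown for a gene is its longest transcript among those tagged as principal by APPRIS in M21.

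The alternatives tried were a tolerance of 1 mismatch, counting only sequences under 1 number, another pool size estimator, leaving out each library in turn, and looser symbol matching. The planned edgeR test of BHLKO against AlbCre per cell type and the test of cell type shares were not run, since they need counts and a map from cells to lungs. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.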

Results

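Single-cell libraries were made from the lungs of 6 male mice to compare animals that lack Bmal1 and Hif1a in the liver (BHLKO, 3 lungs) with animals that carry the albumin-promoter Cre recombinase alone (AlbCre, 3 lungs). Bmal1 encodes a core transcription factor of the circadian clock, and Hif1a encodes the oxygen-regulated subunit of the hypoxia-inducible factor HIF-1. The cell barcodes and the genes available for counting are described here. Differences between BHLKO and AlbCre lungs in expression or in cell composition were not measured.

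The 6 libraries held 24532 cell barcodes, with a median of 3919 per library. Library 3 held the most, 5541 barcodes, and library 5 the fewest, 2684, a ratio of 2.06. Library 4 held 5421 barcodes, library 6 held 4415, library 1 held 3423 and library 2 held 3048. As shares of all barcodes these were 22.6% for library 3 (95% Clopper-Pearson interval 22.1 to 23.1%), 22.1% for library 4 (21.6 to 22.6%), 18.0% for library 6 (17.5 to 18.5%), 13.95% for library 1 (13.5 to 14.4%), 12.4% for library 2 (12.01 to 12.8%) and 10.9% for library 5 (10.6 to 11.3%). The intervals of libraries 3 and 4 overlapped, and no other 2 libraries had overlapping intervals. Because the numbers were not tied to lungs, the yields were not compared between genotypes.

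**Figure D1:**
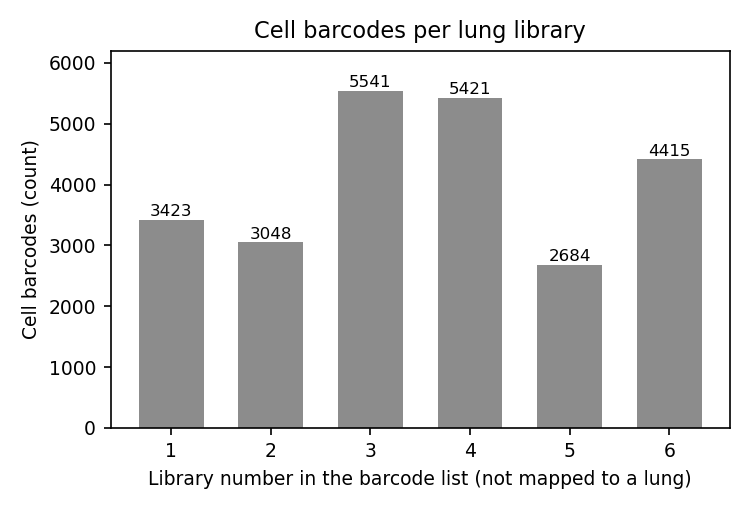
Bars give the number of cell barcodes (vertical axis, count) in each of the 6 libraries (horizontal axis, library number, not mapped to a lung or genotype). Libraries 3 and 4 hold 5541 and 5421 barcodes, and library 5 holds 2684.

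A barcode names a cell only together with its library number, so sharing of sequences between libraries was examined next. The 24532 barcodes comprised 24461 distinct sequences, of which 71 occurred under 2 numbers and 0 under 3 or more. Between 2 and 12 sequences were shared per pair of libraries. Libraries 4 and 5 shared 12, against 4.18 expected from their sizes (2.87-fold, exact binomial adjusted p = 0.0129 over the 15 pairs). None of the other 14 pairs passed this test. Unlike this exact test of single pairs, the one-sided Monte Carlo test over all 15 pairs together did not pass the threshold (p = 0.0936). This call rested on which libraries were included: the Monte Carlo value was 0.0180 without library 2 and 0.0458 without library 6, both past the threshold, and 0.927 without library 4 and 0.781 without library 5. The estimated number of sequences that the libraries drew from was 3479055 (95% Poisson interval 2758169 to 4454568). This estimate assumes independent draws of equally likely sequences. Without the pair of libraries 4 and 5 it was 3940050 (3054475 to 5175788).

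**Figure D2:**
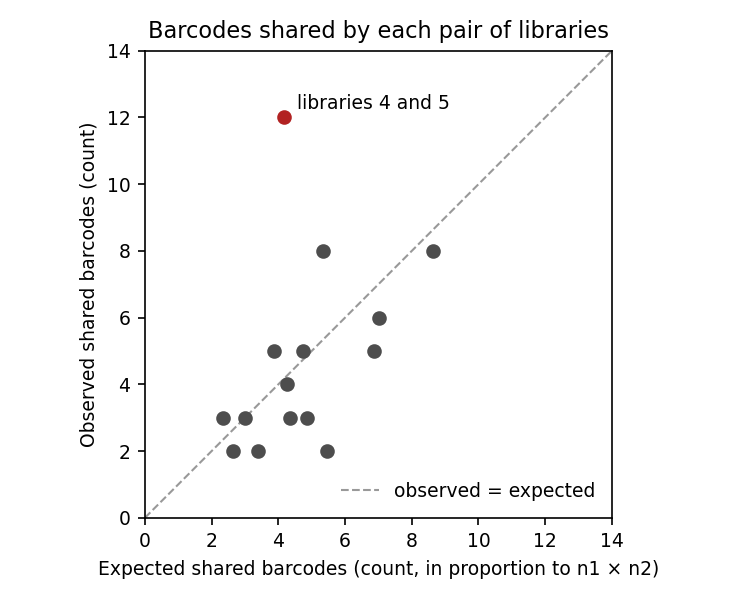
Each point is 1 of the 15 pairs of libraries, with the barcodes expected to be shared in proportion to the product of the library sizes (horizontal axis, count) against those observed (vertical axis, count); points may coincide and the dashed line marks equality. Libraries 4 and 5 share 12 barcodes against 4.18 expected, and the other pairs share 2 to 8.

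The genes deleted in BHLKO livers were both in the gene list under 1 identifier each. Bmal1 was listed under its symbol Arntl (ENSMUSG00000055116), a protein-coding gene on the plus strand of chromosome 7 from 113207465 to 113314126 (GRCm38). The principal transcript Arntl-204 has 21 exons. Its last exon runs from 113313459 to 113314126 and holds a 3′ untranslated region of 507 bases. Hif1a (ENSMUSG00000021109) lies on the plus strand of chromosome 12 from 73901375 to 73947530. Transcript Hif1a-201 has 15 exons, and its last exon, from 73945552 to 73947530, holds a 3′ untranslated region of 1827 bases. Alb (ENSMUSG00000029368), which encodes serum albumin and whose promoter drives the Cre, lies on the plus strand of chromosome 5 from 90460897 to 90476602. Its transcript Alb-201 has 15 exons and a 3′ untranslated region of 169 bases, which an intron divides. None of these genes shares exon bases with another listed gene on the same strand. The list contains no symbol for Cre, and each of its 32285 identifiers is a mouse Ensembl gene. The exons deleted in the livers of BHLKO mice are not given in the sources used here, so whether the 3′ ends lie outside the deleted part is open. The samples were lungs, and expression of these genes was not measured in them.

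**Figure D3:**
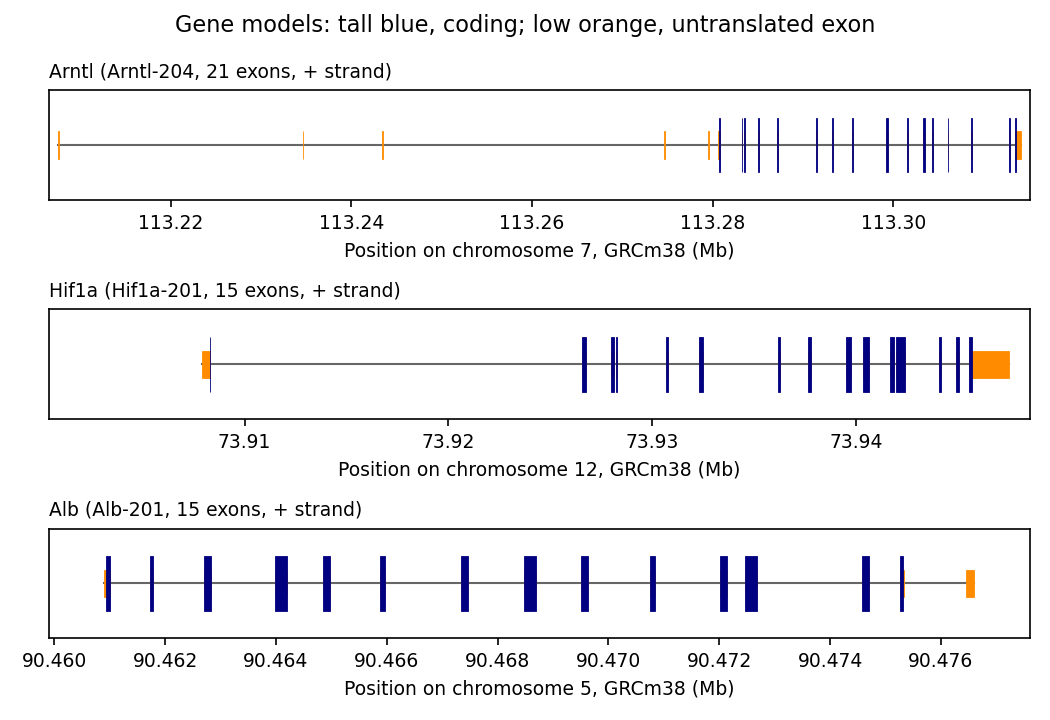
Gene models of Arntl, Hif1a and Alb on GRCm38 (horizontal axes, position in Mb, each panel to its own scale), with coding sequence as tall blue boxes, untranslated exon sequence as low orange boxes and introns as lines. Counted without introns, the 3′ untranslated regions at the right ends hold 507 bases in Arntl, 1827 in Hif1a and 169 in Alb. An intron divides that of Alb.

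All 64 members of the gene groups fixed for this comparison were listed. The clock group had 19 of 19 members. It includes the period genes Per1, Per2 and Per3 and the cryptochromes Cry1 and Cry2, which repress the BMAL1-CLOCK complex, the nuclear receptors Nr1d1 and Nr1d2, which repress Bmal1 transcription, and the output transcription factor Dbp. The hypoxia response group had 20 of 20 members, among them Epas1 (HIF-2α), the prolyl hydroxylases Egln1, Egln2 and Egln3, the angiogenic factor Vegfa, the glucose transporter Slc2a1 and the glycolytic enzymes Ldha and Pgk1. One member, the glycolytic aldolase Aldoa, was listed under 2 identifiers. These are ENSMUSG00000030695 (chromosome 7, 126795234 to 126800751, minus strand) and ENSMUSG00000114515 (chromosome 7, 126800790 to 126809108, minus strand). The vascular tone group had 18 of 18 members, with the nitric oxide synthases Nos1, Nos2 and Nos3, endothelin Edn1 with its receptors Ednra and Ednrb, and the prostacyclin synthase Ptgis. The hepatocyte group had 7 of 7 members, including Apoa1, Ttr and Serpina1a. Serpina1a belongs to a family of near-identical genes, so reads assigned to it would be uncertain. No listed member with a single identifier shared exon bases with another listed gene on its strand.

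The 98 markers of 28 lung cell types or states were also all listed. The list holds 98.5% of the protein-coding genes of M21. Full counts here and in the groups above therefore describe the annotation and not the lungs. Endothelial markers had 5 of 5 members (such as Pecam1 and Cdh5), aerocyte markers 4 of 4 (Car4, Ednrb, Apln, Tbx2) and general capillary markers 4 of 4 (such as Gpihbp1 and Aplnr). Alveolar type 1 markers had 4 of 4 members (such as Ager and Hopx) and alveolar type 2 markers 5 of 5 (such as Sftpc, which encodes surfactant protein C). Alveolar macrophage markers had 4 of 4 (such as Marco and Siglecf) and neutrophil markers 4 of 4 (such as S100a8 and S100a9). Ccl21a, a lymphatic endothelial chemokine, was listed under 2 identifiers, 1 on chromosome 4 and 1 on a scaffold outside the assembled chromosomes. Gata3, an ILC2 marker, shared 77 of its 3978 exon bases (1.94%) with 9230102O04Rik on the same strand. The erythroid markers Hba-a1 and Hba-a2 are near-identical copies on chromosome 11, and reads from them cannot be told apart with certainty. Across the whole list, 38 symbols stood for more than 1 identifier, 78 identifiers in all. Matching by symbol would merge these genes, among which Aldoa and Ccl21a were the only members of the fixed groups.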

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

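Of 95 alternative values for 42 results, 93 kept their call or stayed within bounds, and 2 did not. Most of the 93 could not have changed. They were looser symbol matching of gene lists that were already complete, or a tolerance of 1 mismatch without any such pair. The bounds were the 95% intervals for library sizes and for the pool size, and a factor of 1.5 for other counts. Both changes concern how evenly shared barcodes fell over pairs of libraries. The Monte Carlo p was 0.0936 with all libraries and ranged from 0.0180 without library 2 to 0.927 without library 4. It passed the threshold without library 2 or library 6 (0.0458), and did not pass without library 1, 3, 4 or 5; the cause was not tested. Without the pair of libraries 4 and 5, chosen after seeing the data and for its deviation, it was 0.932, which says nothing about chance in the other pairs. The pool size ranged from 2953828 without library 3 to 4345823 without library 4, was 3199114 as a mean over pairs and 3940050 without the pair of libraries 4 and 5, all inside the main interval. Allowing 1 mismatch changed nothing, because no 2 barcodes were 1 mismatch apart, so this setting tests nothing. Ignoring case and adding synonyms left every gene list at its full size, which exact matching had already reached. No paired analysis was possible because the library numbers were not tied to lungs and counts per gene were not analysed here. For the same reason the 2 planned comparisons of BHLKO with AlbCre and their 5 alternatives were not run.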

Other observations

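The tests of the single pair of libraries 4 and 5 and of carry-over from library 4 were chosen after the result was seen; the tests over all pairs, of carry-over at 1% and of sequencing errors were fixed before.

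The gene list sets which lung transcripts were countable. Its annotation release is not given and it was not made from GENCODE M21 as it stands. A gene of M21 that is absent from the list was therefore not necessarily left out by choice. Relative to M21 the list holds 21702 of 22028 protein-coding genes (98.5%), 5605 of 5854 lincRNAs (95.7%) and 2955 of 2959 antisense genes (99.9%). All 218 immunoglobulin variable genes and all 144 T-cell receptor variable genes are included. It holds 1 of 9941 processed pseudogenes, 0 of 2207 microRNAs and 0 of 1507 snoRNAs. Of 37 mitochondrial genes it holds 13, and neither mitochondrial ribosomal RNA is among them, so a mitochondrial share computed from these data would rest on those 13 genes.

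Of the 326 protein-coding genes of M21 that are not listed by identifier, 19 have their symbol listed under another identifier. The symbol is not listed for the others, of which 247 carry a provisional name (Gm and a number) and 60 another name. Whether such a gene is listed under a different symbol as well as a different identifier was not examined. Genes among the 60, named after the list was seen, include Mx1, an interferon-induced antiviral gene (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907), Tymp, which encodes thymidine phosphorylase (chromosome 15, 89371931 to 89377039), and Rbm12, which encodes an RNA-binding protein (chromosome 2, 156091958 to 156111978).

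Libraries 4 and 5 shared 12 barcode sequences, against 4.18 expected from library size, and for this pair independent draws of beads are argued against (exact binomial adjusted p = 0.0129). Over all 15 pairs the question stays open, because the Monte Carlo value was 0.0936 and fell past the threshold without library 2 (0.0180) or library 6 (0.0458), while it was 0.927 without library 4 and 0.781 without library 5. With 8 extra barcodes in that pair, the Monte Carlo test passed in 59 of 100 simulations at the pool size estimated from the other pairs. It passed in 75 at a larger one. These simulations were set to the observed excess after seeing the data, so they add no independent evidence on chance. Missing the threshold does not by itself show chance. Among barcodes kept after filtering, carry-over or a split library amounting to 1% of the smaller library's barcodes is argued against in every pair. The highest upper 95% limit was 0.781%, in libraries 4 and 5. A split here means 1 set of beads under 2 numbers. Carried reads whose barcodes were filtered out cannot be seen, so carry-over of reads is not bounded. Whether library 4 shared more with all others, through a low level of carry-over, stays undecided. Library 4 shared 26 barcodes with libraries 1, 2, 3 and 6, against 22.6 expected from all pairs but that of libraries 4 and 5. This was 1.15-fold with an interval of 0.751 to 1.69, which includes 1, so no excess was shown. The 4 pairs compared are among the 14 that gave the expectation, which pulls the ratio toward 1. The interval also treats that expectation as exact, so a small excess is not excluded. After allowing for its choice among 15 pairs, the rate of libraries 4 and 5 was not separated from that of these 4 pairs (exact binomial p times 15 = 0.0680). A shared sequence has no direction, and carry-over in that pair alone was not tested. No biological explanation was tested.

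No 2 barcodes were 1 mismatch apart, either among 53884352 pairs within libraries (0 pairs) or among 247012894 pairs between them (0 pairs). Sequences of random bases would give 3.36 such pairs in all and 0.602 within libraries, with a Poisson probability of 0.0346 for 0 in all. The shared sequences point to a limited pool, estimated at 3479055. These values decide nothing here, because whether that pool holds sequences 1 mismatch apart is not known. The planned comparison of the rate within libraries with that between them could not be computed, since both are 0. With 0 such pairs, no kept barcode is a copy of another in its library with 1 base changed. Errors of more than 1 base were not examined, and errors in barcodes that were not kept cannot be seen.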
